A study of Homo sapiens with 6 samples.

How the data were processed

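Gene expression was measured on 6 arrays of 2 human pancreatic ductal adenocarcinoma cell lines, Panc1 and BxPC3. For Panc1 there was 1 control array and 1 array of cells in which KDM6A had been knocked out, and for BxPC3 there were 2 control and 2 knockout arrays. Per the labels' protocols, a lentiviral vector carried Cas9 and a guide against KDM6A, infected cells were selected with puromycin, and knockout clones were isolated by limiting dilution. The sources used here do not say whether the control cells carried a vector, how many clones the knockout arrays stand for, or whether the 2 arrays of a BxPC3 group came from separate cultures. A p-value therefore measures only the spread between those arrays, which may be technical. Per the labels' protocols, total RNA with an integrity number above 7 was labelled with biotin in a kit that primes from the 3' end of transcripts.

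The deposited values are log2 expression summaries of probe sets, 1 column per array. Per the submitters' processing notes they were made with RMA in the affy package, and no version is given in the sources used here. RMA subtracts background, brings the probe distributions of the arrays it is given onto each other and summarises the probes of a set. Exactly equal values on a pair of arrays occurred at 2895 probe sets between the Panc1 arrays and at 629 to 846 probe sets between pairs of BxPC3 arrays. There were 0 such probe sets between arrays of different lines, a pattern that 2 separate RMA runs would leave. Levels were therefore compared within a line only, and contrasts between lines were contrasts of the knockout differences. Such quantile scaling removes any change that shifts most genes one way, and RMA keeps dim probe sets at a background level instead of at 0, which understates their differences.

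The table held 54613 probe sets. The platform annotation gave 1 gene symbol to 41091 probe sets, several symbols to 1801 and none to 11721, and gene names were used only from the first kind. Of these, 41037 were matched by gene identifier to the RefSeq gene table and 0 symbols needed updating. A gene was represented by its probe set with the highest mean over the 6 arrays, and was tested where that probe set exceeded the median of all probe sets of an array on at least 1 of the 6 arrays. This left 14387 of 19775 genes. Probe sets whose identifiers end in _x_at or _s_at can hybridise to several similar transcripts, so values of close paralogs are uncertain.

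BxPC3 knockout and control arrays were compared with limma, version 3.58.1, in R 4.3.3. The fit had 1 mean for each of the 4 groups and 2 residual degrees of freedom, which come from the BxPC3 arrays alone, and eBayes added 3.08 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted. Panc1 had 1 array per group, so that its differences have no replicate check and were given without a p-value, as counts of genes differing at least 2-fold. Knockout against control over both lines was tested in limma with cell line and genotype as terms, which leaves 3 residual degrees of freedom. The difference between the lines' knockout effects was tested as an interaction contrast in the 4-group fit, on the assumption that Panc1 arrays vary as BxPC3 arrays do.

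Before the data were examined, 34 gene lists were fixed for chromatin complexes, cell cycle, tumour subtype, signalling, metabolism and markers of other cell types. They held 700 entries, of which 76 had no probe set with a single symbol and were not analysed here. An entry was matched by a synonym only where that name is not the symbol of another gene. The endocrine list was left with fewer than 5 measured genes and was not tested. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 33 lists tested, of which 1 is not reported. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run as alternatives. For Panc1, the median of a list was placed among 10000 random lists of the same size matched on mean expression over all 6 arrays in 10 bins. Random lists do not hold genes that move together, so the percentiles are descriptive only. The genes named were also fixed by rule. They are KDM6A, KDM6B and CDKN1A, the 12 higher and 12 lower genes with the largest changes among those past the threshold in BxPC3, and those past the threshold over both lines with the same sign in both, up to 12 per direction. They also include the 12 higher and 12 lower genes with the largest differences in Panc1, the 6 genes with the smallest adjusted p for the interaction, and 4 members of each list described, by smallest p or, for Panc1, by largest difference. Genes named outside this rule are marked as chosen after their values were seen.

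The same steps were tested on simulated data, 10 sets of 14387 genes with 200 changed. In BxPC3 the limma test recovered 79.3% of genes changed by 0.5 and 99.8% of those changed by 1 on the log2 scale, and 6.72% of its calls were false. Over both lines the shares were 94.9% and 100%, with 6.57% false calls. For the interaction they were 3.1% and 83.7%, with 7.17% false calls. The spread of the real Panc1 arrays is not known, and a difference between the lines' effects adds to the residual of the fit over both lines. The shares over both lines and for the interaction may therefore not hold for the real data. A list shifted by -0.3 was recovered in 100% of 20 simulations with the preset correlation and in 0% with the estimated one, and 2 of 640 unshifted lists were called with the preset correlation. Losing a call with the estimated correlation therefore says little about a list with a shift of that size. Larger shifts were not simulated, so for lists with larger shifts the loss cannot be set aside. The interferon list had an estimated correlation of 0.457 in BxPC3, above the preset one. In BxPC3 the duct list had an estimated correlation of -0.0056, below the preset 0.01, and still lost its call.

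Alternatives fixed before the data were examined changed the filter, the summary of probe sets, the scaling of arrays, the variance prior, the threshold, the arrays in the fit, the weight of the lines and the list test. Wherever arrays were centred, the median was that of the tested genes of an array, not that of all its probe sets. Cyclic loess within each line and a crossed pairing of the BxPC3 arrays were added after the data were seen. Precision is limited by the number of arrays.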

Results

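The arrays show how loss of KDM6A, a histone demethylase of the COMPASS-like complex, went with gene expression in 2 pancreatic cancer lines, and the series title singles out the cyclin-dependent kinase inhibitor gene CDKN1A. Panc1 and BxPC3 are both established from pancreatic ductal adenocarcinomas. Panc1 was measured on 1 control and 1 knockout array, and BxPC3 on 2 of each. All values are RMA summaries on the log2 scale, with array medians between 4.75 and 5.06. Differences are knockout minus control, and errors are standard errors from limma with 2 arrays per BxPC3 group. The BxPC3 control arrays correlated at 0.998 and differed with an SD of 0.158 over probe sets, and the knockout arrays correlated at 0.996 and differed with an SD of 0.230.

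KDM6A itself was lower in the knockout arrays of both lines. On its brightest probe set the level in BxPC3 fell from 7.93 in control to 7.15 in knockout arrays, a difference of -0.79 ± 0.12 (SE, adjusted p = 0.0329). In Panc1 it was 6.73 on the control and 4.06 on the knockout array, a difference of -2.67. Another probe set of KDM6A gave -2.31 in Panc1 and was also lower in BxPC3. A further one was lower in BxPC3 and differed by 0.18 in Panc1, where it read 3.06 and 3.25, below the median of either array. The last probe set was below the array median on all 6 arrays and gave 0.07 and 0.00. Where these probe sets lie relative to the guide's target was not analysed here, and a frameshift need not lower a transcript, so the levels are only a partial check of the genotype labels. The BxPC3 call of KDM6A ended without control array 1 (adjusted p = 0.215), without control array 2 (0.147) and without knockout array 2 (0.0843), and with no filter on dim probe sets (0.0611). Its paralog KDM6B differed by -0.16 ± 0.13 in BxPC3 (adjusted p = 0.546) and by 0.04 in Panc1, where its other probe sets ranged down to -0.83.

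CDKN1A, measured by 1 probe set, fell from 9.95 to 8.82 in BxPC3, a difference of -1.14 ± 0.07 (adjusted p = 0.0036), or 2.20-fold. In Panc1 it was 8.48 on the control and 7.45 on the knockout array, a difference of -1.03. Tested over both lines the difference was -1.10 (adjusted p = 0.0227), and the effects of the lines did not pass the test for a difference (interaction adjusted p = 0.589). The BxPC3 call held without any one array, with adjusted p between 0.0277 and 0.0480. The call over both lines ended with each array centred on its median (adjusted p = 0.0768) and without any one BxPC3 array, with adjusted p between 0.188 and 0.338.

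**Figure D1:**
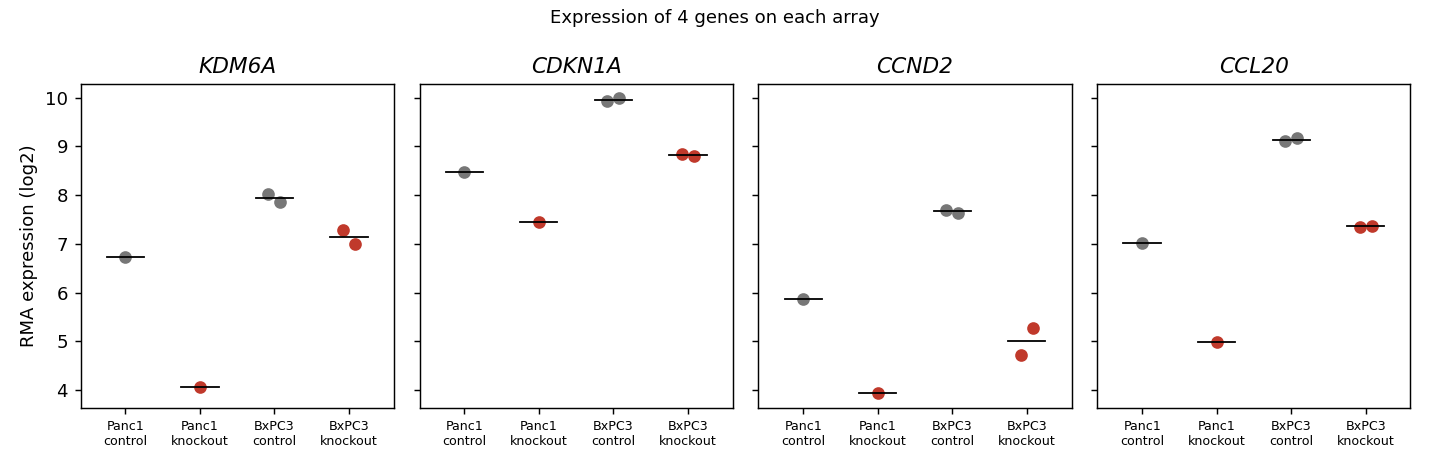
RMA expression on the log2 scale (vertical axis) of KDM6A, CDKN1A, CCND2 and CCL20 on each of the 6 arrays, by line and genotype (horizontal axis). Each point is an array and each line the group mean; all 4 genes lie lower on the knockout arrays of both lines, with differences for CDKN1A of -1.14 in BxPC3 and -1.03 in Panc1.

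In BxPC3, 679 of 14387 tested genes changed at an adjusted p under 0.05, of which 515 fell and 164 rose. Among those that also changed at least 2-fold, 146 fell and 20 rose. The genes that fell most included CA2 (-3.21 ± 0.21) and CA13 (-2.66 ± 0.07), carbonic anhydrases, and SPP1 (-2.69 ± 0.17), which encodes the secreted phosphoprotein osteopontin. GPNMB, a transmembrane glycoprotein (-3.15 ± 0.18), CLCA2, a chloride channel accessory protein (-3.15 ± 0.20), and SDC2, a heparan sulfate proteoglycan (-2.77 ± 0.09), also fell. Genes of keratinising epithelium were among them, with S100A7 at -2.66 ± 0.08, S100A8 at -2.62 ± 0.09 and SPRR2B at -2.46 ± 0.13. SPRR2B is read by a probe set that can hybridise to its paralogs. SCGB1A1, a secretoglobin of airway club cells, fell from 10.34 to 7.20. The cancer-testis gene SPANXB1 (-3.14 ± 0.14) and CCND2, which encodes a D-type cyclin (-2.67 ± 0.18), fell as well. Of these 12 genes, 9 were below the array median on both knockout arrays, where RMA compresses differences.

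The gene that rose most in BxPC3 was ITGBL1, an integrin beta-like protein, from 5.00 to 7.68 (2.69 ± 0.12). It was followed by RERG, a RAS-like growth inhibitor (2.20 ± 0.27), SPINK4, a secreted protease inhibitor (2.11 ± 0.10), NBEA, the membrane-trafficking protein neurobeachin (1.59 ± 0.11), and NALCN, a sodium leak channel (1.48 ± 0.18). The cancer-testis genes MAGEB2 and MAGEA11 rose by 1.47 and 1.36, IGFBP5 by 1.45, the Wnt inhibitor APCDD1 by 1.31 and AASS, an enzyme of lysine breakdown, by 1.29. CMAHP (1.44) and FAM230C (1.37) also rose. On both control arrays 4 of these 12 genes were below the array median. Other probe sets above the array median on some arrays gave 0.44 to 1.31 for IGFBP5, 1.06 for NBEA, -0.38 for CA13, -0.59 and -2.49 for SDC2, -1.62 for CCND2 and -2.08 to -4.28 for CLCA2. A dim probe set of NALCN gave -0.36. Adjusted p of these 24 genes, from limma, lay between 0.0016 and 0.0191. Each differed in the same direction in both knockout arrays against both control arrays, which follows from selecting large changes and is no separate check.

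The number of BxPC3 calls depended on single arrays. It was 94 without control array 1, 89 without control array 2 and 318 without knockout array 2, with 1 residual degree of freedom in each, and 1317 when the variance prior followed expression. Of the 24 named genes, 18 and 19 stayed past the threshold without control array 1 and control array 2, and 23 without either knockout array. The calls lost in one or more of these were RERG, NALCN, IGFBP5, CMAHP, MAGEA11 and AASS, all genes that rose.

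Genes of the interferon response were lower as a group in BxPC3 knockout arrays. All 28 measured members of the list lay below 0, with a median of -0.75, and 20 of them fell, or 26 adjusted over the list alone. RSAD2 (-2.12 ± 0.09) and IFIT1 (-1.52 ± 0.09), antiviral effectors, USP18 (-1.47 ± 0.10), a deconjugase of the ubiquitin-like protein made by ISG15, and HERC6 (-0.78 ± 0.06), a ubiquitin ligase family member, had the smallest p. The list's camera adjusted p was 2.3e-21, and its adjusted p = 0.555 with an estimated correlation. Antigen presentation genes had a median of -0.54 over 15 members, 8 of which fell, or 9 adjusted over the list alone (camera adjusted p = 1.7e-06, adjusted p = 0.555 with an estimated correlation). Among them were the class I heavy chains HLA-B (-0.89 ± 0.07) and HLA-C (-0.60 ± 0.06), the peptide transporter subunit TAP1 (-0.66 ± 0.07) and the immunoproteasome subunit PSMB9 (-0.60 ± 0.06). HLA heavy chains are near-identical, so their probe sets may read each other. Cytokines and other genes downstream of NF-kB had a median of -0.48 over 24 members, 11 of which fell, or 16 adjusted over the list alone (camera adjusted p = 6.1e-10, adjusted p = 0.555 with an estimated correlation). The chemokine CCL20 (-1.78 ± 0.07), the cytokines IL1A (-0.87 ± 0.07) and IL1B (-0.90 ± 0.06) and the siderophore-binding LCN2 (-0.88 ± 0.08) were among these.

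Lists of differentiation and adhesion also shifted in BxPC3. The squamous or basal subtype list had a median of -0.46 over 18 genes, with 9 falling and 1 rising, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.569 with an estimated correlation). KRT14, a basal keratin (-2.26 ± 0.09), and SPRR3, a cornified envelope protein (-2.37 ± 0.09), fell beside S100A7 and S100A8. Pancreatic duct genes had a median of -0.53 over 8 members, 4 of which fell both over all genes and adjusted over the list alone (camera adjusted p = 0.0282, adjusted p = 0.555 with an estimated correlation), namely CA2, SPP1, MUC1 (-1.26 ± 0.13) and the transcription factor SOX9 (-0.97 ± 0.07). In the epithelial junction list, median -0.11 over 24 genes, 4 fell, or 10 adjusted over the list alone. These 4 were the claudins CLDN4 (-0.85 ± 0.09) and CLDN7 (-0.53 ± 0.07), OCLN (-0.67 ± 0.08) and TJP3 (-0.89 ± 0.09), with a camera adjusted p = 0.00034 and adjusted p = 0.570 with an estimated correlation. Matrix proteases and plasminogen genes had a median of -0.38 over 17 members, with 8 falling and 1 rising, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000622, adjusted p = 0.555 with an estimated correlation). PLAT, tissue plasminogen activator (-2.18 ± 0.08), MMP7 (-1.27 ± 0.12), the urokinase receptor PLAUR (-0.75 ± 0.08) and CTSB (-0.47 ± 0.07) were among those that fell.

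The mitotic cell cycle list was the 1 list of the 11 past the camera threshold that shifted up in BxPC3, with a median of 0.17 and 21 of 24 members above 0. None of its members rose over all genes and 5 did adjusted over the list alone (camera adjusted p = 8.0e-06, adjusted p = 0.570 with an estimated correlation); the kinesins CENPE and KIF20A differed by 0.35 ± 0.07 and 0.32 ± 0.07. Over the 19 ribosome biogenesis and MYC target genes the median was -0.12, and 0 members passed over all genes or adjusted over the list alone (camera adjusted p = 0.00744, adjusted p = 0.570 with an estimated correlation). MYC differed by -0.26 ± 0.07 (adjusted p = 0.116). BCL2 family genes had a median of -0.13 over 14 members, 2 of which fell, or 5 adjusted over the list alone, namely the survival factor BCL2A1 (-1.32 ± 0.13) and the pro-apoptotic BIK (-0.66 ± 0.07) over all genes (camera adjusted p = 0.00747, adjusted p = 0.555 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.07 over 23 members with 3 falling, or 5 falling and 1 rising adjusted over the list alone, with EGLN3 at -1.12 ± 0.07, NDRG1 at -0.54 ± 0.09 and SLC2A1 at -0.46 ± 0.06 (camera adjusted p = 0.0471, adjusted p = 0.555 with an estimated correlation). Fry kept 7 of the 11 lists at adjusted p between 0.0281 and 0.0285, namely interferon response, antigen presentation, NF-kB cytokines, squamous or basal, duct, matrix proteases and BCL2 family. Without knockout array 1 the camera calls of the duct (adjusted p = 0.155), matrix protease (0.0686), hypoxia (0.0999) and BCL2 family (0.0606) lists ended. Hypoxia also ended without control array 2 (0.0629) and without knockout array 2 (0.168), ribosome biogenesis without control array 2 (0.068), and the squamous or basal, duct and hypoxia lists with a stricter filter on dim probe sets (0.112, 0.149 and 0.0821).

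The other 22 lists tested did not pass the camera threshold in BxPC3. Among chromatin and cycle lists, medians were -8.5e-05 for the KDM6 and COMPASS-like complex, where KDM6A was the 1 member past the threshold, 0.08 for Polycomb group, 0.02 for histone deacetylases, -0.05 for CDK inhibitors, -0.09 for p53 targets and 0.06 for DNA replication. CDKN2D (-0.52 ± 0.08) was the CDK inhibitor that fell beside CDKN1A, and HDAC9 (-0.64 ± 0.08) the 1 deacetylase that fell. Medians were -0.12 for replication-dependent histones, 0.02 for HOX genes, 0.01 for the classical subtype, -0.09 for acinar genes, 0.00 for mesenchymal genes, 0.04 for integrins and 0.01 for TGF-beta and activin. They were -0.08 for cholesterol synthesis, -0.01 for the unfolded protein and ATF4 response, -0.10 for Wnt and stemness and -0.21 for NRF2 targets. Among markers of other cell types, medians were 0.05 for fibroblasts and stellate cells, 0.07 for immune cells, 0.03 for endothelium and -0.12 for neural cells. The endothelial cadherin CDH5 fell by 2.19 on the log2 scale and was the 1 endothelial marker past the threshold; the mean of that list was -0.22 against its median of 0.03. Mean and median also differed in sign for the integrin and TGF-beta lists.

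In Panc1, 472 genes were at least 2-fold lower and 83 at least 2-fold higher on the knockout array. Between the BxPC3 group means, which average 2 arrays each and so are less noisy, 153 were lower and 20 higher. The pairs of arrays within either BxPC3 group held 0 genes with a 2-fold difference. Panc1 has 1 array per group, so these differences have no replicate check. The genes most raised were KIT, a receptor tyrosine kinase, at 3.63 on the control and 7.89 on the knockout array (4.25), COBLL1 (3.51), the phosphatase PPM1H (3.29) and ID2, an inhibitor of helix-loop-helix transcription factors (3.05). UGT8 (2.82), DSE (2.51), PRRG4 (2.44), DIPK1A (2.23), the tissue factor gene F3 (2.13), GUCY1B1 (1.96), RNF144B (1.94) and EPHX4 (1.91) followed. Of these 12 genes, 8 were below the array median on the control array.

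The lowest on the Panc1 knockout array relative to control were PDLIM1, a cytoskeletal adaptor (11.16 to 6.68, -4.49), the interferon-induced membrane protein IFITM1 (-4.42) and the ion channel TRPA1 (-4.32). CHST15 (-3.79), the transcription factors KLF4 (-3.73) and KLF12 (-3.19), the proteoglycan SRGN (-3.32), TRBC1 (-3.29), the desmosomal protein DSP (-3.28), CLMP (-3.04), the cholesterol exporter ABCA1 (-3.01) and IGFBP2 (-2.99) came next. On the knockout array 6 of these 12 genes were below the array median, where RMA compresses differences. Other probe sets of COBLL1 (0.78 and 0.71), KLF4 (-0.24), KLF12 (-0.36 and 0.35), TRBC1 (-1.22 and -0.35) and CLMP (-1.05) gave smaller differences, in 1 case of the other sign. Centring each array on the median of its tested genes raised all Panc1 differences, whose median over genes was 0 before, by 0.197. It gave 301 lower and 152 higher genes. The split was 378 lower and 98 higher with quantile normalization and 445 lower and 91 higher with cyclic loess, so that lower genes stayed in excess under each scaling.

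Relative to random lists matched on mean expression over all 6 arrays, 12 of the 33 lists stood apart on the Panc1 arrays. The Panc1 difference varied with the Panc1 level, with medians of 0.14 in bin 2 and -0.14 in bin 5 of 10. The matching may not remove this trend. Interferon response genes had a median of -0.61, below all 10000 random lists, and 6 of 28 were at least 2-fold lower, among them IFITM1, IFIT2 (-2.03) and IFIT3 (-1.64). NF-kB cytokines (median -0.48, with CCL20 at -2.02 and CXCL8 at -1.55), cholesterol synthesis (-0.75, with STARD4 at -2.08 and INSIG1 at -1.71) and the unfolded protein and ATF4 response (-0.65, with ATF3 at -1.76 and ASNS at -1.52) also lay below all 10000. The p53 target list had a median of -0.40, at the 0.08th percentile, with TP53INP1 at -1.60 and PLK2 at -1.27. Mitotic cell cycle (0.41) and DNA replication genes (0.30, with RRM2 at 1.15) lay above all random lists, and ribosome biogenesis and MYC targets (0.19) at the 99.5th percentile with 19 of 19 members above 0. Epithelial junction (-0.22, with DSP and CDH1, -2.08), mesenchymal (-0.22, with CDH11 at -1.32) and BCL2 family genes (-0.28, with PMAIP1 at -0.72) lay between the 1.5th and 1.7th percentile. The mesenchymal median was 0.00 with no filter on dim probe sets, and the BCL2 family median was -0.01 with probe sets averaged. With centred arrays, which shift a list and its random lists alike, these 3 medians were -0.02 for epithelial junction, -0.02 for mesenchymal and -0.08 for BCL2 family genes, and the same number of lists, 12, stood apart. Fibroblast and stellate markers had a median of 0.31, at the 99.6th percentile, but a mean of 0.04 and a median of -0.04 with probe sets averaged, and COL5A2 was lower (-1.22).

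**Figure D2:**
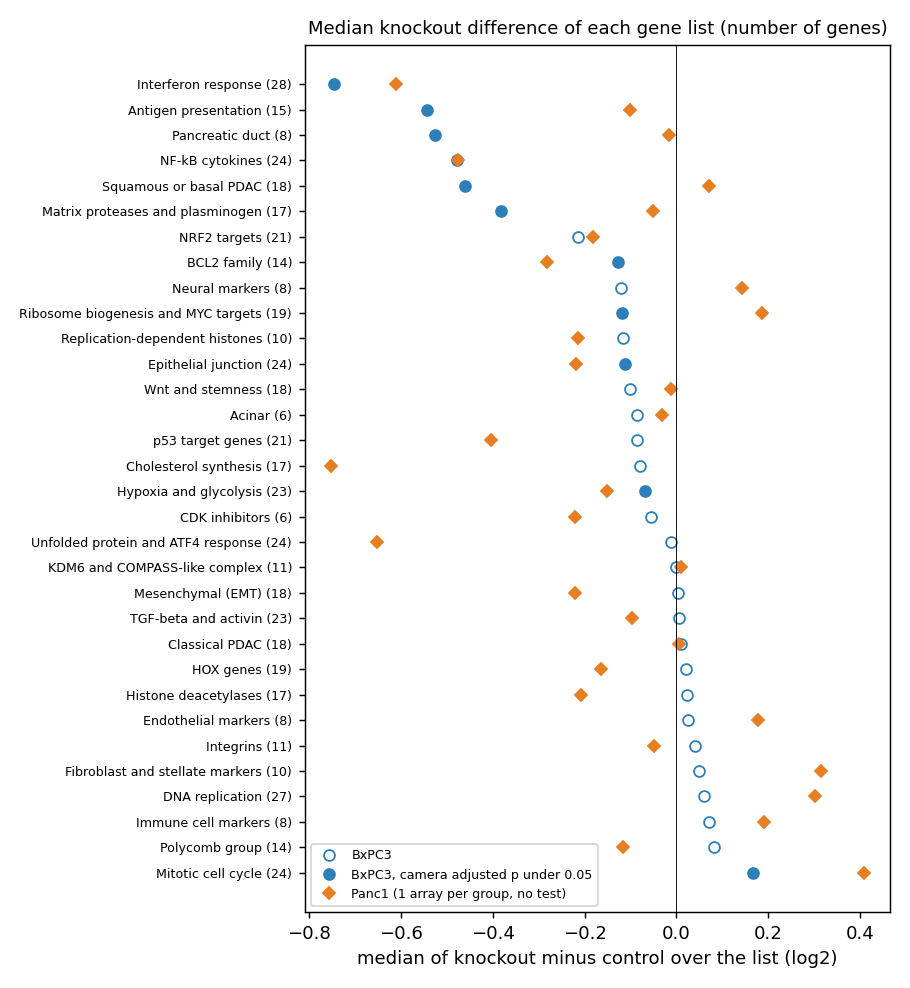
Median difference of knockout minus control (log2, horizontal axis) over the measured genes of each gene list shown (vertical axis, number of genes in brackets), for BxPC3 as circles and Panc1 as diamonds. Filled circles mark the 11 lists with a camera adjusted p under 0.05 in BxPC3; the interferon response list lies at -0.75 in BxPC3 and -0.61 in Panc1.

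Over both lines, 12 genes changed by limma with cell line as a term, and all 12 fell. They were CCND2 (-2.43), NREP (-1.86), the chemokine CCL20 (-1.86), the lysosomal protein LAMP3 (-1.83), CLIC3 (-1.71), TNFSF9, a ligand of the tumour necrosis factor family (-1.70), the complement factor gene CFB (-1.63), SERPINB1, an inhibitor of neutrophil proteases (-1.24), the interferon-induced exonuclease ISG20 (-1.22), CDKN1A (-1.10), the secreted CTHRC1 (-1.09) and CRIP2 (-0.96). Their adjusted p lay between 0.0117 for CCL20 and 0.0483 for CTHRC1. In BxPC3 the 12 genes differed by -1.01 to -2.67 and in Panc1 by -0.87 to -2.02. The test favours genes whose effects are alike in the lines, since a difference between the lines adds to its residual. At an unadjusted p under 0.05, 1162 genes were lower and 542 higher. CCND2 in Panc1 rests on 1 of its probe sets (-1.93), since another gave -0.10. With arrays centred on their medians 4 genes passed, and with quantile normalization 6. Without any one BxPC3 array 0 genes passed, with 905 to 2027 at an unadjusted p under 0.05. Without either Panc1 array the same fit tests BxPC3 alone and called 679. With equal weight for each line in the 4-group fit, whose spread comes from BxPC3 alone, 2093 genes passed, 1572 lower and 521 higher.

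Of the lists, 14 passed camera over both lines at the preset correlation, and 0 passed with an estimated correlation, where 5 had an unadjusted p under 0.05. Those lower were interferon response (median -0.63), NF-kB cytokines (-0.49), matrix proteases (-0.37), antigen presentation (-0.35), cholesterol synthesis (-0.28), BCL2 family (-0.24), the unfolded protein and ATF4 response (-0.24), epithelial junction (-0.21), histones (-0.19), p53 targets (-0.19), NRF2 targets (-0.17) and hypoxia (-0.14). Those higher were mitotic cell cycle (0.26) and DNA replication (0.16). Over all genes CCL20, in the NF-kB list, was the 1 member of these lists that fell, and adjusted over the list alone 21 interferon, 8 NF-kB, 8 matrix protease and 6 antigen presentation genes fell. XAF1 (-0.77), IFI6 (-0.72) and IFIH1 (-0.92) had adjusted p of 0.0712, 0.0997 and 0.124. The interferon and NF-kB lists had adjusted p = 0.0893 with an estimated correlation, and the other 12 had adjusted p between 0.328 and 0.532 with an estimated correlation. Fry over both lines kept interferon response (adjusted p = 0.00775), NF-kB cytokines (0.00154), BCL2 family (0.00154), NRF2 targets (0.0184) and matrix proteases (0.0444). It did not keep the rest, with adjusted p from 0.0501 for epithelial junction to 0.281 for cholesterol synthesis. CDK inhibitors, which camera did not call, passed fry (0.0217). Without either Panc1 array the camera calls of p53 targets, DNA replication, cholesterol synthesis, the unfolded protein response, NRF2 targets and histones ended, with adjusted p between 0.0508 and 0.700. Histones also ended without BxPC3 control array 1 (0.0736), knockout array 1 (0.0762) or knockout array 2 (0.0553), and matrix proteases without knockout array 1 (0.071).

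Across genes the knockout effects of the lines were nearly unrelated, with Pearson's r = 0.05 and Spearman's rho = 0.03 over 14387 genes, which are not independent replicates. Without BxPC3 knockout array 2 r was -0.0122, and without knockout array 1 it was 0.106. The SD of the differences was 0.454 in Panc1, between single arrays, and 0.269 in BxPC3, between means of 2 arrays. Over all probe sets, single pairs of a control and a knockout array differed with an SD of 0.388 in Panc1 and 0.245 to 0.284 in BxPC3. Of the 515 genes that fell in BxPC3, 293 (56.9%) were also lower in Panc1, where 49.4% of all genes lay below 0. Of the 164 that rose, 68 (41.5%) were also higher, where 48.7% of all genes lay above 0. These shares were not tested against each other and depend on the scaling of the arrays. At a 2-fold difference in each line 16 genes were lower in both, where independent lists of these sizes would share 5.02, and 0 were higher in both, against 0.115. These 16 include 9 of the 12 genes that fell over both lines, as well as CA2, IGFBP2 and LOXL1. Opposite 2-fold differences occurred in 5 genes, CCL2, DNER, ID3, LIPG and MAN1A1, which were lower in BxPC3 and higher in Panc1 and were chosen after their values were seen.

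The difference between the lines' effects passed the limma interaction test at 2008 genes, 1300 with the lower and 708 with the higher effect in Panc1. Quantile normalization (1430 lower, 1125 higher) and cyclic loess (1630 and 1099) kept this majority. Centring each array on the median of its tested genes, which adds a constant to all knockout differences of a line, gave 1002 lower and 1985 higher. The 6 genes with the smallest adjusted p (0.0022 to 0.0034) were PDLIM1, IFITM1, SRGN, TRPA1, KLF4 and PON3, with interaction values of -4.54, -3.90, -3.29, -4.34, -3.62 and -2.85. TRPA1 was below the median of each BxPC3 array, where a fall could hardly show. KDM6A differed too, by -1.88 (adjusted p = 0.0111). Lists that passed camera for the interaction were cholesterol synthesis (median -0.61) and the unfolded protein and ATF4 response (-0.64), lower in Panc1, and mitotic cell cycle (0.25), DNA replication (0.26), ribosome biogenesis (0.33), squamous or basal (0.79) and antigen presentation (0.32), higher in Panc1. Each had adjusted p between 0.800 and 0.889 with an estimated correlation. The squamous or basal value sets a BxPC3 median of -0.46 beside a Panc1 median of 0.07. Its members S100A7 and S100A8 lay below the median of both Panc1 arrays, where a fall could hardly show. The limma interaction test takes the spread of the Panc1 arrays from BxPC3, and 2 of its gene calls would remain if Panc1 arrays varied 2 times as much. Without BxPC3 control array 1 it called 247 genes, without control array 2 it called 234 and without knockout array 2 it called 3402.

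**Figure D3:**
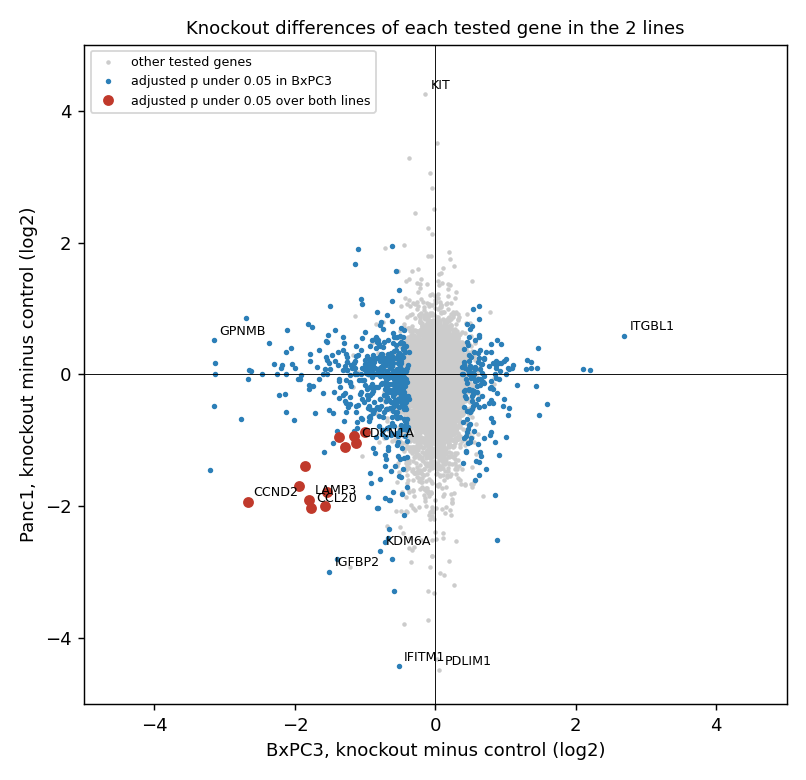
Knockout minus control difference (log2) of each of the 14387 tested genes in BxPC3 (horizontal axis) and Panc1 (vertical axis). Points are genes, coloured by whether they passed the limma test in BxPC3 or over both lines; the 12 genes past the threshold over both lines lie lower in both, while PDLIM1 (-4.49) and KIT (4.25) lie far from 0 on the Panc1 axis only.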

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

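Tests chosen only after the result was seen were those on the brighter genes, on clone or culture differences and on a larger spread of the Panc1 arrays; the cyclic loess setting was added after the data were seen, and bounds for the remaining tests were written before their results.

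The difference between the lines' knockout effects passed the interaction test at 2008 genes, and among the named genes the direction was as follows (Panc1 effect minus BxPC3 effect, log2). The Panc1 effect was the higher one by 4.39 for KIT, 3.66 for PPM1H, 3.49 for COBLL1, 3.13 for ID2, 2.88 for UGT8, 2.74 for PRRG4, 2.64 for EPHX4, 2.56 for RNF144B, 2.53 for DSE, 2.41 for GUCY1B1, 2.33 for DIPK1A and 2.18 for F3. The Panc1 effect was the lower one by -4.54 for PDLIM1, -4.34 for TRPA1, -3.90 for IFITM1, -3.62 for KLF4, -3.47 for KLF12, -3.34 for CHST15, -3.29 for SRGN, -3.18 for DSP, -3.16 for CLMP, -3.07 for ABCA1, -2.85 for PON3, -2.70 for TRBC1, -1.88 for KDM6A and -1.48 for IGFBP2. Genes that fell in BxPC3 had positive values, 3.67 for GPNMB, 3.55 for SPP1, 3.31 for SPANXB1, 3.14 for SCGB1A1, 2.73 for S100A7, 2.68 for CLCA2, 2.67 for S100A8, 2.60 for CA13, 2.46 for SPRR2B, 2.09 for SDC2 and 1.77 for CA2. All of these but CA13, SDC2 and CA2 were below the median of both Panc1 arrays. A fall of those dim genes could hardly show in Panc1, so their values need not mean a different response. Genes that rose in BxPC3 had negative values, -2.13 for RERG, -2.10 for ITGBL1, -2.09 for NALCN, -2.04 for NBEA, -2.02 for SPINK4, -1.61 for CMAHP, -1.36 for IGFBP5, -1.27 for FAM230C, -1.21 for AASS, -1.09 for APCDD1 and -1.06 for MAGEB2. Median interaction values of the lists past the threshold were 0.79 for squamous or basal, 0.33 for ribosome biogenesis and MYC targets, 0.32 for antigen presentation, 0.26 for DNA replication, 0.25 for mitotic cell cycle, -0.61 for cholesterol synthesis and -0.64 for the unfolded protein and ATF4 response. All 7 lists lost their call with adjusted p between 0.800 and 0.889 with an estimated correlation. That setting recovered 0% of lists shifted by -0.3 in the simulations, and larger shifts were not simulated. The simulations therefore do not show whether the lost calls reflect that setting or the lists, and whether these lists differ stays open.

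The first pattern weighed is this lack of agreement between the lines. For noise hiding a shared effect, r with the Panc1 difference was taken among BxPC3 calls of at least 2-fold and was 0.0796. This cannot decide the question, since noise is small against the effect on the BxPC3 side only. The noise of the Panc1 difference was not measured. Some of these genes, such as SCGB1A1 and SPRR2B, were also too dim in Panc1 for a fall to show. An intensity trend between arrays is argued against as the whole cause, since r over all genes was 0.058 after cyclic loess within each line. A larger spread of the Panc1 arrays stays open for the individual calls, because Panc1 has no replicate; 0.0996% of the calls would remain at 2 times the BxPC3 spread. That the lines respond differently to loss of KDM6A, or that their clones differ for other reasons, remains untested.

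The second pattern is the excess of lower over higher genes in Panc1, 472 against 83. An intensity trend between the 2 arrays is argued against as the whole cause, since the ratio of lower to higher genes was 4.89 after cyclic loess. Dim probe sets are argued against as the whole cause, since the ratio was 3.83 among the brighter genes, but they may add to its size, since in the 2 brightest of 10 bins the counts were 14 against 7 and 11 against 4. The excess was 301 against 152 with centred arrays and 378 against 98 with quantile normalization, so its size, though not its direction, varied with the scaling. A response to loss of KDM6A and a property of the clone measured cannot be separated with 1 array per group.

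The third pattern is the lower interferon response list in the knockout arrays of both lines. An intensity trend is argued against, since after cyclic loess the median nearer to 0 of the 2 lines was -0.562. Spread between replicate arrays is argued against for BxPC3, since the larger within-group median was 14% of the knockout difference. A clone or culture difference unrelated to KDM6A stays open and cannot be told apart from the knockout, since each line has 1 knockout group and 2 lines moving one way are too few to decide. A lower interferon response after loss of KDM6A may be one hypothesis, untested beyond these arrays.

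The 12 genes past the threshold over both lines were set beside the other splits of the 6 arrays into 3 and 3 with cell line in the fit. The real split was 1 of 10 with a count that large and the highest other count was 0, but 10 splits are too few for a share under 0.05.

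Signals also appeared in probe sets outside the gene comparisons. In BxPC3, 8 probe sets with no gene name here passed the threshold among 3891 tested, 7 lower and 1 higher. Of 1283 tested probe sets with several gene names 36 passed, 20 lower and 16 higher.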

How the results depend on the processing

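Cyclic loess and crossed pairing were chosen after the data were seen. The tests have 2 or 3 residual degrees of freedom, and probe sets near background have compressed differences. The other sign was taken by KDM6A on dim probe sets, by the correlation between the lines without BxPC3 knockout array 2 (-0.0122), by KDM6B in BxPC3 and over both lines without that array, and with probe sets averaged by the fibroblast list, COL1A1 and KDM6B in Panc1 and by TP53INP1 and IDI1 in BxPC3. Apart from the results below, 2908 of 3455 single gene and list values under the alternatives kept their direction and side of the threshold or moved by less than the replicate spread, 245 passed the threshold no more, 146 passed it newly and 156 moved by more than the spread. Where a cause is not named it was not tested.

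Genes changed in BxPC3 (679) numbered 445 with no filter, 1317 with the prior following expression, 166 with a 2-fold minimum and 1181 at adjusted p under 0.1. They ranged from 89 to 610 without 1 array, where a lone array is assumed to vary like the others. Cyclic loess gave 911, of which 669 were among the 679. Genes differing 2-fold in Panc1 (555) numbered 323 with probe sets averaged, 1009 with each probe set on its own, 1843 at 1.5-fold and 2597 by limma with the spread of BxPC3. Genes changed over both lines (12) numbered 4 with centred arrays, 6 with quantile normalization, 28 with the prior following expression, 39 at adjusted p under 0.1 and 2093 with equal weight of the lines (521 higher), and ranged from 0 to 679 without 1 array. Interaction genes (2008) numbered 1042 with no filter, 3335 with each probe set on its own, 3324 with the prior following expression, 733 with a 2-fold minimum and 3713 at adjusted p under 0.1. With centred arrays they numbered 2987, of which 1985 were higher and 1002 lower in Panc1, against 708 and 1300, since centring adds a constant to all genes of a line. Quantile normalization (1125 higher, 1430 lower) and cyclic loess (1099 and 1630) kept the majority lower. They ranged from 234 to 3402 without 1 array.

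The share of BxPC3 calls with the same sign in Panc1 (53.2%) was 50.1% with no filter, 47.6% with centred arrays, 50.7% with each probe set on its own and 56.8% with cyclic loess, and ranged from 48.4% to 55.4% without 1 array. Of the 11 lists in BxPC3, 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) and 7 with fry, and 7 to 11 passed without 1 array. Of the 14 lists over both lines, 0 passed with an estimated correlation. Fry kept only interferon response, NF-kB cytokines, matrix proteases, BCL2 family and NRF2 targets among them.

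KDM6A in BxPC3 kept -0.79 with no filter but not its call, and ranged from -0.93 to -0.65 without 1 array. Its probe set below the median of all arrays gave 0.0705. In Panc1 KDM6A (-2.67) was -1.20 with probe sets averaged, -2.48 with centred arrays and -2.48 with quantile normalization, and its other probe sets gave -2.31, 0.18 and 0.00, the latter 2 dim on both Panc1 arrays. KDM6A over both lines (-1.42, adjusted p = 0.275) passed at -1.73 with equal weight and at -0.79 without either Panc1 array, and ranged from -1.68 to -0.79. CDKN1A over both lines (-1.10) was -1.02 with centred arrays and ranged from -1.14 to -1.07 without 1 array, and in Panc1 (-1.03) it was -0.84 with centred arrays.

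Same-numbered BxPC3 arrays did not deviate together (r = -0.166 across genes), so the numbers were not taken to pair the arrays. With the replicate block 384 genes passed in BxPC3 (368 of them among the 679), 0 over both lines (1106 at an unadjusted p under 0.05) and 852 for the interaction, and CDKN1A over both lines was -1.10 at adjusted p = 0.159. With the crossed pairing as a block 455 genes passed in BxPC3.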

Other observations

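Families of related genes were looked up by symbol after the BxPC3 results were seen. The serpin B family, intracellular protease inhibitors, had 6 of 8 members lower at adjusted p under 0.05 in BxPC3, with SERPINB7 at -1.65 ± 0.18, SERPINB1 at -1.38 ± 0.07, SERPINB9 at -0.93 ± 0.13 and SERPINB3 at -0.81 ± 0.12. Small proline-rich genes of the cornified envelope had 5 of 7 members lower, among them SPRR2C (-2.12 ± 0.13) and SPRR1B (-0.93 ± 0.07), whose probe sets can share transcripts. In the S100 family 4 of 14 fell, S100A9 (-2.14 ± 0.17) and S100A4 (-1.05 ± 0.07) beside S100A7 and S100A8. Since the families were chosen for genes already seen to fall, no p-value of a family as a group is given. Among the members looked up, 0 were at least 2-fold lower or higher in Panc1. S100P, a family member that the lookup left out, was lower there (-1.98). S100A7 (4.34 and 4.42), S100A8 (4.35 and 4.40) and SPRR2B (4.13 on each) were below the median of both Panc1 arrays. A fall of these genes could hardly show there.

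Of 18 chemokines, 9 were lower and 1 higher in BxPC3. CXCL17 (-1.79 ± 0.19), CCL2 (-1.05 ± 0.13), CXCL10 (-0.94 ± 0.10) and CXCL11 (-0.83 ± 0.09) fell beside CCL20, and CCL21 rose (0.69 ± 0.08). In Panc1, 5 chemokines were at least 2-fold lower, among them CCL20, CXCL8 and CXCL3 (-1.39), and CCL2 was higher (1.14). Collagens went both ways, with COL6A1 (1.00 ± 0.07), COL5A2 (0.91 ± 0.07) and COL12A1 (0.69 ± 0.10) higher and COL8A1 (-0.98 ± 0.08) lower in BxPC3. COL6A1 (-0.95) and COL5A2 (-1.22) were lower in Panc1. Among keratins KRT14, KRT23 (-1.27 ± 0.10) and KRT16 (-0.53 ± 0.07) fell and KRT13 rose (0.87 ± 0.09) in BxPC3.

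Several S100, SPRR and other epidermal genes neighbour each other on chromosome 1, and a copy number or regional difference in the knockout clones was tested as a hypothesis of shifted runs of 21 neighbouring genes, with bounds written before the result. Windows of 20 genes had been planned, and 21 were used. In Panc1 0 of 13888 windows passed the 95th percentile of the largest median over 1000 gene-order permutations, which was 0.51. This argues only against regional shifts with a median past 0.51 between the Panc1 arrays, and smaller ones stay open. In BxPC3 13 windows passed, in a run of 33 genes from MRPL9 to CHTOP on chromosome 1 (median -0.16, 23 genes below 0) and a run of 21 genes from EIF3J to SHC4 on chromosome 15 (median -0.22, 16 below 0). The run on chromosome 1 may in part restate the S100 and SPRR falls already seen. The same test on control array 2 against control array 1 also passed, in 6 windows on chromosome 6 from KCNK5 to TAF8 (median -0.08), and knockout array 2 against knockout array 1 gave 0 windows, so that a window past the threshold may also arise between arrays of 1 group, and the regional hypothesis stays open in BxPC3.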
